A study of Homo sapiens with 24 samples.

How the data were processed

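The data came from H2052, a human cell line established from a pleural mesothelioma, a tumour of the lining of the lung. Cells were transfected with 20 nM of a microRNA mimic that carried biotin at its 3′ end, with the lipid reagent RNAiMAX. The mimic was either miR-497-5p, a member of the miR-15/16 family, or a scrambled control sequence. Labels of the treated libraries write it as miR-497-5p-RE, a suffix whose meaning is not given in the sources used here. Cells were collected after 12 h and after 72 h. From each collection, per the labels' protocols, RNA of the cells was sequenced as the input (called RNA-seq here), and RNA that streptavidin beads retained from a cytoplasmic extract through the biotin was sequenced as the pull-down. Both kinds of library were made from poly(A) RNA, so transcripts without a poly(A) tail, such as most replication-dependent histone mRNAs, are poorly sampled.

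Per the submitters' processing notes, reads of 150 bases from both ends were trimmed with Trimmomatic 0.36, aligned to GRCh38 with STAR 2.5.2b and assigned to genes with featureCounts of Subread 1.5.2, keeping uniquely placed reads within exons. The deposited files, 1 per library, hold whole-number counts for 57500 gene identifiers and no normalized values. Because only uniquely placed reads were kept, genes with near-identical copies, such as ribosomal protein genes with processed pseudogenes, tubulins and histones, lose reads to an unknown degree. The sources used here do not state whether strand was used in counting, so reads of overlapping and antisense genes cannot be told apart. Gene symbols, positions and 3′ UTRs were taken from GENCODE release 44 on GRCh38, which held 56410 of the identifiers (98.1%).

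The labels put the 24 libraries in 8 groups of 3, by assay, time and mimic. Total counts ranged from 21561816 to 30602007 in the RNA-seq libraries and from 8262425 to 30650982 in the pull-down libraries. The lowest correlation between libraries of 1 group was 0.953. Differences between libraries of 1 group exceeded counting error, with a chi-square per degree of freedom of 1.77 to 8.45 in RNA-seq and of 7.1 to 32.5 in the pull-down. The biological coefficient of variation was 0.06 over the RNA-seq libraries and 0.349 over the pull-down libraries, so the pull-down detects only larger differences. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

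The counts of each assay were fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling, its default filter on low counts and the robust quasi-likelihood test, over the 12 libraries of that assay. Contrasts compared miR-497-5p with control at each time and the effect at 72 h with that at 12 h. A further fit over the 12 libraries of each time tested the pull-down effect minus the RNA-seq effect, called enrichment beyond the input. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and every adjusted p for a gene below is from these fits. Values are log2 fold changes, miR-497-5p over control, ± the standard error, and CPM (counts scaled to a common library total) are scaled by TMM with the SD of 3 libraries unless said otherwise. The overlap of calls was tested with Fisher's exact test, two-sided, beside the number that independent lists give. Genes are not independent replicates, so that p describes these libraries.

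The 27 lists of named genes were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. With the preset value 14, 13, 5 and 12 lists passed at RNA-seq 12 h, RNA-seq 72 h, pull-down 12 h and pull-down 72 h. With an estimated correlation 3, 4, 2 and 2 passed. A further 2 groups of genes were defined by sites for the miR-497-5p seed. The guide CAGCAGCACACUGUGGUUUGU pairs through its seed with TGCTGCT (a 7mer-m8 site), with TGCTGCTA (an 8mer site), with GCTGCTA (a 7mer-A1 site) and with GCTGCT (a 6mer site). Sites were searched in the longest annotated 3′ UTR of each protein-coding gene. The seed effect is the median log2 fold change of genes with a 7mer-m8 or 8mer site minus that of genes without a 6mer site, with a bootstrap standard error of 1000 draws. It was ranked among 210 words of 7 bases with the same base composition.

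The samples' groups, the tests, the lists, the main alternatives and the rule for genes named in the text were set before the data were examined. The rule takes the 6 genes that the series' title and design name, the 8 largest changes in each direction among genes with a mean of at least 5 CPM and non-overlapping arms, up to 4 members of each list with the smallest adjusted p, the 8 foremost genes of each overlap, and the 5 largest changes in each direction of the contrasts between times and between assays. Other genes named were chosen after their values were seen, which is said where they appear.

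The fits were tested on simulated counts with 100 genes changed 1.5-fold and 100 changed 2-fold. In RNA-seq at 12 h 98% and 100% were recovered, at 72 h 95% and 100%. In the pull-down at 12 h 39% and 67% were recovered, and at 72 h 27% and 78%. Between 2.8% and 7.1% of the simulated calls were false. A simulated shift was given to 3 words over 13947 genes, and all 3 were ranked first.

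The labels give replicate numbers 1 to 3 in every group. Deviations from the group means were correlated between same-numbered libraries of the groups compared. All 3 pairs exceeded 0.1 only between the 2 arms of RNA-seq at 12 h (0.13, 0.12 and 0.52), although replicate 2 correlated more with another number (0.17). The numbers were taken to pair the samples in that comparison alone, and the fit with the number as a block is printed there where it changes a call.

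Alternatives were DESeq2 1.42.0, limma-voom with quality weights, DESeq2-style size factors in edgeR, library totals without scaling, no filter on low counts, a fit of 6 libraries at a time, the replicate number as a block, and each library left out in turn. Scaling by library totals moved the median of all genes by -0.107 in RNA-seq at 72 h, by 0.121 in the contrast between assays at 12 h and by 0.135 in that at 72 h. An offset for transcript length and a restriction to genes present at 72 h were added after the data were seen. The values of some genes chosen by these rules are not reported here. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the site search, the ranks and the plots.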

Results

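The series asked which transcripts miR-497-5p binds in pleural mesothelioma cells and which transcripts change in amount when it is added. H2052 cells received biotinylated miR-497-5p or a scrambled control mimic. At 12 h and 72 h both the RNA of the cells (RNA-seq) and the RNA retained with the biotin (pull-down) were sequenced, with 3 libraries in each of 8 groups. In RNA-seq, control libraries held 26432049 to 30602007 counts at 12 h and 25535580 to 27595617 at 72 h. Libraries with miR-497-5p held 22185600 to 29707303 and 21561816 to 23597532 counts. Control pull-down libraries held 18127272 to 18910429 counts at 12 h and 23552252 to 30650982 at 72 h. With miR-497-5p they held 15771995 to 23916035 and 8262425 to 22358295, the lowest being replicate 2 at 72 h. A gene was called when its adjusted p in edgeR's quasi-likelihood test was under 0.05, and each value below rests on 3 libraries per arm.

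Of the 6 genes that the series itself names, WEE1 (ENSG00000166483, chromosome 11, 9573681 to 9593457 in GRCh38), a kinase that holds CDK1 inactive before mitosis, fell in RNA-seq from 33.9 ± 2.17 to 24.4 ± 1.67 CPM at 12 h (log2 fold change -0.47 ± 0.07, adjusted p 2.8e-06). It fell further, from 18.6 ± 0.398 to 9.69 ± 1.41 CPM, at 72 h (-0.95 ± 0.09, adjusted p 2.62e-13). In the pull-down at 12 h WEE1 rose from 13.5 ± 2.8 to 44.4 ± 12.3 CPM (1.71 ± 0.3, adjusted p 0.00538). At 72 h its pull-down value was 0.29 ± 0.32 (adjusted p 0.604). PKMYT1 (ENSG00000127564, chromosome 16, 2968024 to 2980539), the other kinase of this family, had no site for the seed in its 3′ UTR. Its values at 12 h were 0.02 (adjusted p 0.874) in RNA-seq and -0.42 ± 0.22 (adjusted p 0.549) in the pull-down. By 72 h PKMYT1 had fallen from 14.5 ± 1.39 to 2.9 ± 0.395 CPM in RNA-seq (-2.31 ± 0.1, adjusted p 1.19e-23) and from 15.4 ± 4.45 to 2.67 ± 1.32 CPM in the pull-down (-2.65 ± 0.27, adjusted p 5.62e-08).

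The series' design text calls CDK4, CCND1 and VEGFA known targets and GAPDH a housekeeping gene. CDK4 (ENSG00000135446, chromosome 12, 57747727 to 57756013) is a kinase that drives cells out of G1. It had -0.04 in RNA-seq at 12 h (adjusted p 0.509) and fell from 111 ± 3.44 to 27.1 ± 2.08 CPM at 72 h (-2.03 ± 0.05, adjusted p 5.5e-35). Its pull-down values were -0.2 ± 0.15 at 12 h (adjusted p 0.755) and -1.14 ± 0.2 at 72 h (adjusted p 8.76e-05). CCND1 (ENSG00000110092, chromosome 11, 69641087 to 69654474) encodes cyclin D1, the partner of CDK4. It fell from 686 ± 19.8 to 549 ± 18.1 CPM in RNA-seq at 12 h (-0.32 ± 0.03, adjusted p 2.1e-10). At 72 h CCND1 stood at 0.03 (adjusted p 0.403), which became -0.07 when scaled by library totals (adjusted p 0.023), while its pull-down value rose by 0.59 ± 0.09 (adjusted p 3.62e-05). VEGFA (ENSG00000112715, chromosome 6, 43770184 to 43786487) encodes a growth factor for blood vessels and was lower in RNA-seq at 72 h (-0.21 ± 0.07, adjusted p 0.0127). That call ended without control replicate 3 (adjusted p 0.113) or miR-497-5p replicate 1 (adjusted p 0.0975). In the pull-down at 12 h VEGFA had 0.87 ± 0.28 (adjusted p 0.212, and 0.0228 when adjusted over the list of published targets alone). GAPDH (ENSG00000111640, chromosome 12, 6533927 to 6538374) rose in RNA-seq by 0.12 ± 0.03 at 12 h (adjusted p 0.00107, and 0.0721 with the replicate block and an offset for transcript length). At 72 h GAPDH rose by 0.7 ± 0.03 in RNA-seq (adjusted p 1.08e-26) and by 0.45 ± 0.1 in the pull-down (adjusted p 0.00136).

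**Figure D1:**
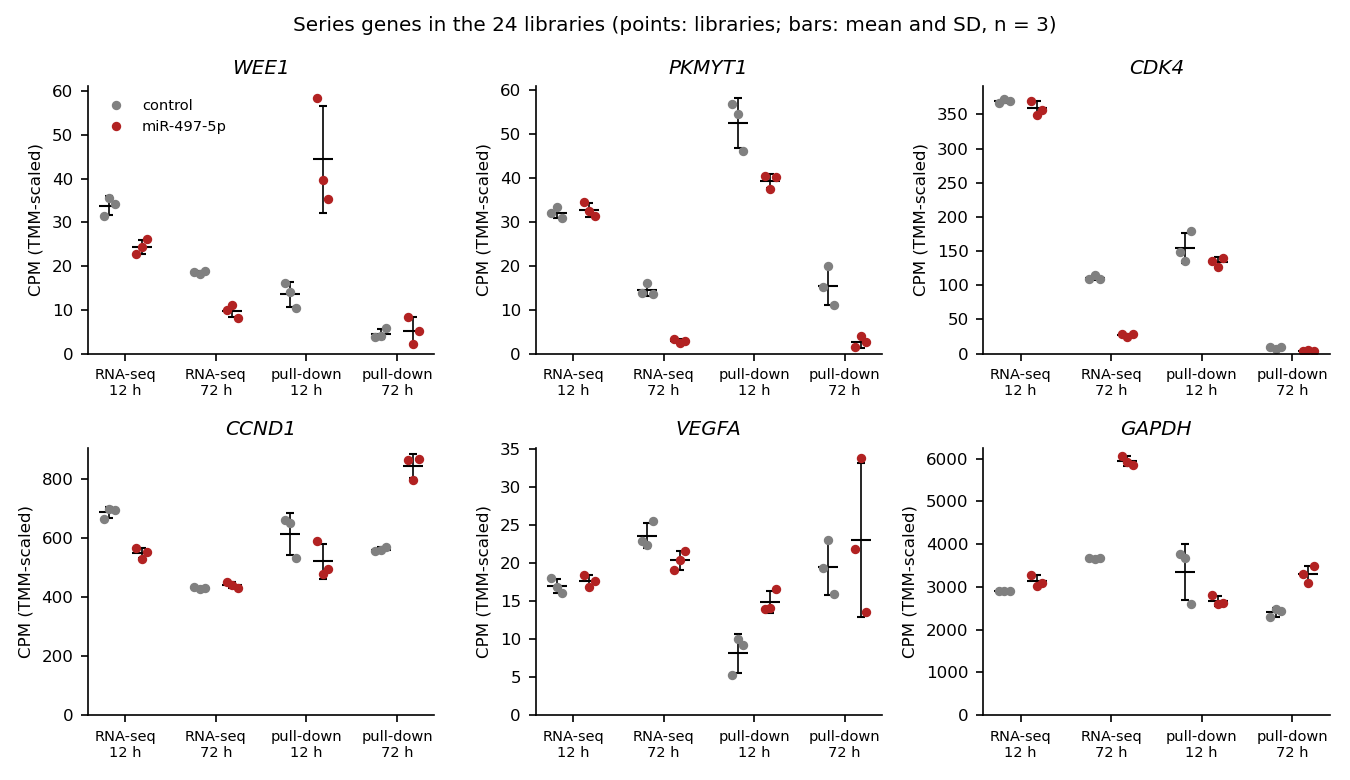
TMM-scaled CPM (vertical axis) of the 6 genes named by the series in each library, by assay and time (horizontal axis), with points for libraries, bars for the mean and SD of 3 libraries, grey for control and red for miR-497-5p. WEE1 falls in RNA-seq at 12 h from 33.9 to 24.4 CPM while it rises in the pull-down from 13.5 to 44.4 CPM, and PKMYT1 falls in both assays at 72 h.

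At 12 h the question for RNA-seq was which transcripts change first. CCNE1, cyclin E1 of the G1/S transition and a published target of the miR-15/16 family, fell from 22.5 ± 0.261 to 13.7 ± 0.972 CPM (-0.71 ± 0.07, adjusted p 1.25e-09). CDK6, the G1 kinase related to CDK4, fell from 46.6 ± 3.69 to 30.2 ± 2.98 CPM (-0.63 ± 0.06, adjusted p 2.85e-10). CDC25A, a phosphatase that activates CDKs, fell from 26.9 ± 1.28 to 17.9 ± 0.73 CPM (-0.59 ± 0.07, adjusted p 1.06e-08). RRAS2, a Ras-related GTPase, rose from 394 ± 13.1 to 679 ± 3.32 CPM (0.79 ± 0.03, adjusted p 5.88e-24). Among 17335 genes tested 1256 were higher and 919 lower. Most changes were small, with a median size of 0.21 among called genes, and 20 of the higher and 38 of the lower changed at least 2-fold. Arms of 3 did not overlap for 25.7% of genes, against 10% by chance. The balance of directions depended on scaling, with 722 higher and 1746 lower when scaled by library totals. Without control replicate 2 the lower genes numbered 590.

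Of the 33 published targets of the family tested in RNA-seq at 12 h, 19 fell (20 when adjusted over the list alone). The list as a whole shifted down (median -0.24, camera adjusted p 9.01e-14, and adjusted p = 0.00224 with an estimated correlation). Besides CCNE1 and CDK6 these included SMURF2, a ubiquitin ligase of TGF-β signalling (-0.39 ± 0.03, adjusted p 7.01e-12) and the survival gene BCL2 (-0.61 ± 0.13, adjusted p 0.000715). The published target HMGA2, a chromatin protein, stood at 0.00 ± 0.04 (adjusted p 0.974). Among 21 G1/S genes 5 fell (7 when adjusted over the list alone, with 2 higher; camera adjusted p 0.00158, adjusted p = 0.0581 with an estimated correlation). Of 18 genes of homologous recombination 2 fell (3 when adjusted over the list alone and 4 when scaled by library totals; camera adjusted p 0.0112, adjusted p = 0.0565 with an estimated correlation). In the microRNA pathway 4 of 13 genes fell (6 when adjusted over the list alone), including the Argonaute genes AGO2 (-0.27 ± 0.04, adjusted p 7.96e-06) and AGO1 (adjusted p 0.00042). That list had a camera adjusted p of 0.00228, and adjusted p = 0.0561 with an estimated correlation.

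Transcripts of the protein synthesis and energy machinery rose together at 12 h by small amounts. Of 80 cytosolic ribosomal protein genes 75 were higher (76 when adjusted over the list alone; median 0.22), such as RPL31, from 630 ± 27.8 to 788 ± 22.8 CPM (0.32 ± 0.03, adjusted p 3.57e-11). Their camera adjusted p was 2.6e-45, and adjusted p = 0.0561 with an estimated correlation. Ribosomal protein mRNAs are short, and fold changes at 12 h fell with transcript length across genes (Spearman rho -0.252 ± 0.007). Of 77 nuclear genes of the respiratory chain 53 rose (66 higher and 1 lower when adjusted over the list alone; median 0.18; camera adjusted p 3.81e-27, adjusted p = 0.0431 with an estimated correlation). COX7C (0.3 ± 0.04, adjusted p 4.44e-08) and ATP5F1E (0.31 ± 0.03, adjusted p 4.95e-09) were among them. Of 13 mRNAs encoded in mitochondrial DNA 10 rose (12 when adjusted over the list alone and 6 when scaled by library totals; camera adjusted p 4.91e-09, adjusted p = 0.14 with an estimated correlation). MT-CO2 led them (0.4 ± 0.03, adjusted p 1.14e-15). Inflammatory genes moved the same way, with 7 of 23 higher (10 when adjusted over the list alone; camera adjusted p 5.13e-05, adjusted p = 0.0431 with an estimated correlation). They included the chemokines CCL2 (0.59 ± 0.09, adjusted p 3.48e-06) and CXCL8 (0.46 ± 0.07, adjusted p 1.31e-05). Of 20 genes of the integrated stress and unfolded protein responses 6 rose and 1 fell (7 and 1 when adjusted over the list alone; camera adjusted p 0.00309, adjusted p = 0.0581 with an estimated correlation). DDIT3 was among the higher (0.36 ± 0.06, adjusted p 2.18e-05).

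Among called genes with a mean of at least 5 CPM and arms that did not overlap, the largest fall in RNA-seq at 12 h was that of SPRR3, a cornified envelope protein of stratified squamous epithelium, a tissue this cell line does not come from. It went from 17.8 ± 3.96 to 0.618 ± 0.455 CPM (-4.86 ± 0.53, adjusted p 0.00894, and 0.0702 with the replicate number as a block). Of 27 markers of squamous epithelium tested, chosen after these genes had been seen, 9 were lower. Levels varied between libraries of 1 group: the sum over these markers, in CPM of total counts, was 684, 684 and 239 in the control libraries and 808, 31.3 and 81.3 in those with miR-497-5p. In the pull-down at 12 h the sums were 49.4, 197 and 707 in control and 748, 671 and 78.4 with miR-497-5p.

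By 72 h 57.5% of tested genes were called in RNA-seq. BIRC5, which encodes survivin of the chromosomal passenger complex, fell from 426 ± 5.68 to 131 ± 2.39 CPM (-1.7 ± 0.03, adjusted p 2.07e-37). FOXM1, a transcription factor of mitotic genes, fell from 217 ± 5.24 to 72.1 ± 1.91 CPM (-1.59 ± 0.04, adjusted p 3.1e-34). CKS1B, a small subunit of CDK complexes, went from 76.9 ± 0.951 to 15.5 ± 0.998 CPM (-2.31 ± 0.05, adjusted p 1.99e-35). MMP1, interstitial collagenase, rose from 20 ± 0.937 to 155 ± 8.2 CPM (2.96 ± 0.05, adjusted p 6.92e-40). SERPINB2, an inhibitor of plasminogen activators, rose from 9.69 ± 0.214 to 76.7 ± 2.24 CPM (2.99 ± 0.07, adjusted p 5.5e-35) and DUSP6, a phosphatase that acts on ERK, from 3.43 ± 0.305 to 22.6 ± 0.271 CPM (2.72 ± 0.11, adjusted p 8.49e-25). In all, 4835 genes were higher and 5128 lower of 17335 tested, with 787 and 825 changed at least 2-fold and a median size of 0.54 among called genes. Arms did not overlap for 63.8% of genes (10% by chance). Scaled by library totals the calls were 3808 higher and 6137 lower.

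Proliferation genes fell as groups at 72 h. Of 40 genes of G2/M and mitosis 36 were lower and 1 higher (the same numbers when adjusted over the list alone; median -0.74; camera adjusted p 1.01e-13, adjusted p = 0.0302 with an estimated correlation). Of 37 DNA replication genes 31 were lower (31 when adjusted over the list alone; median -0.7; camera adjusted p 1.82e-09, adjusted p = 0.00355 with an estimated correlation). They included TYMS, thymidylate synthase (-1.46 ± 0.04, adjusted p 1.25e-30), and TK1, thymidine kinase (-1.47 ± 0.05, adjusted p 3.34e-27). Checkpoint signalling had 14 of 20 genes lower and 1 higher (14 and 1 when adjusted over the list alone; camera adjusted p 0.000978, adjusted p = 0.0302 with an estimated correlation). Homologous recombination had 13 of 18 lower and 1 higher (13 and 1 when adjusted over the list alone; camera adjusted p 0.000374, adjusted p = 0.0302 with an estimated correlation). G1/S genes split into 13 lower and 5 higher of 21 (13 and 5 when adjusted over the list alone; camera adjusted p 0.0143, adjusted p = 0.145 with an estimated correlation). CDK2 was among the lower (-1.52 ± 0.06, adjusted p 1.33e-24). The CDK inhibitor CDKN1A, a p53 target, fell too (-0.56 ± 0.04, adjusted p 4.33e-18). The 25 p53 targets went both ways, 6 higher and 12 lower (6 and 12 when adjusted over the list alone; camera adjusted p 0.102).

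Inflammatory, glycolytic and metabolic genes also separated at 72 h. Of 23 inflammatory genes 14 rose and 6 fell (14 and 7 when adjusted over the list alone; median 0.73; camera adjusted p 0.00612, adjusted p = 0.0885 with an estimated correlation). IL1B rose from 92.3 ± 0.987 to 296 ± 3.17 CPM (1.68 ± 0.04, adjusted p 3.7e-34), CXCL8 by 1.9 ± 0.07 (adjusted p 4.89e-22) and IL6 by 1.36 ± 0.07 (adjusted p 3.22e-22). Hypoxia and glycolysis genes were higher in 14 and lower in 2 of 20 (14 and 2 when adjusted over the list alone; camera adjusted p 0.00199, adjusted p = 0.0548 with an estimated correlation). LDHA, lactate dehydrogenase, stood at 0.77 ± 0.03 (adjusted p 2.53e-26). Of 23 cholesterol synthesis genes 16 fell and 4 rose (16 and 4 when adjusted over the list alone; camera adjusted p 0.0095, adjusted p = 0.0885 with an estimated correlation). Genes of the integrated stress and unfolded protein responses went both ways, 8 higher and 8 lower of 20 (8 and 8 when adjusted over the list alone; camera adjusted p 0.889). SLC7A5, an amino acid transporter that responds to ATF4, fell by 1.76 ± 0.04 (adjusted p 8.9e-36).

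The respiratory chain split by genome at 72 h. Of its 77 nuclear genes 49 fell and 11 rose (49 and 12 when adjusted over the list alone, 56 and 6 when scaled by library totals; median -0.24; camera adjusted p 3.85e-05, adjusted p = 0.232 with an estimated correlation). NDUFB9 had -0.99 ± 0.04 (adjusted p 1.84e-27). Of the 13 mitochondrially encoded mRNAs 12 rose (12 when adjusted over the list alone; median 0.73; camera adjusted p 5.29e-07, adjusted p = 0.179 with an estimated correlation). MT-ND2 went from 2753 ± 81.8 to 5956 ± 64.9 CPM (1.11 ± 0.03, adjusted p 6.88e-31). Mitochondrial transcripts took 5.75% to 6.01% of counts in control libraries and 8.51% to 8.85% with miR-497-5p. Ribosomal protein genes went both ways, 40 higher and 28 lower of 80 (40 and 28 when adjusted over the list alone; median 0.07, which became -0.03 when scaled by library totals; camera adjusted p 0.0472, adjusted p = 0.804 with an estimated correlation).

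The published targets went both ways at 72 h, with 20 of 33 lower and 8 higher (20 and 8 when adjusted over the list alone, 22 and 5 when scaled by library totals; median -0.37; camera adjusted p 0.0103, adjusted p = 0.0885 with an estimated correlation). ARL2, a GTPase of tubulin folding, fell from 158 ± 3.19 to 37.3 ± 2.88 CPM (-2.08 ± 0.05, adjusted p 3.1e-34) and FASN, fatty acid synthase, by 1.4 ± 0.04 on the log2 scale (adjusted p 1.53e-29). HMGA2 rose from 43.6 ± 1.65 to 201 ± 8.74 CPM (2.2 ± 0.05, adjusted p 5.6e-36), and it rose in the pull-down too (2.07 ± 0.14, adjusted p 5.78e-11). The longest annotated 3′ UTR of HMGA2, the one searched, holds 7mer-m8 sites at 65952547 to 65952553 and 65958589 to 65958595 of chromosome 12. The gene runs on to 65966295, so transcripts that end there need not carry these sites. Of 25 mesenchymal and matrix genes 10 were higher and 6 lower (10 and 6 when adjusted over the list alone; median 0.1, which became -0.01 with 9 and 9 when scaled by library totals; camera adjusted p 0.158). VIM, the intermediate filament vimentin, rose from 1839 ± 21.5 to 3925 ± 49.7 CPM (1.09 ± 0.03, adjusted p 5.86e-34) and LOX, which crosslinks collagen, by 1.43 ± 0.03 (adjusted p 3.14e-34).

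The pull-down at 12 h asked which transcripts were held with miR-497-5p more than with the control mimic. CCNE1 rose from 17.9 ± 3.47 to 48.8 ± 8.25 CPM (1.45 ± 0.19, adjusted p 0.00022), beside WEE1. E2F3, a transcription factor of S phase, rose from 11.4 ± 0.789 to 24.1 ± 4.52 CPM (1.08 ± 0.18, adjusted p 0.00209). THBS1, thrombospondin 1, rose from 30.1 ± 15 to 133 ± 6.58 CPM (2.14 ± 0.27, adjusted p 0.00106) and ITGB4, an integrin of hemidesmosomes, from 6.14 ± 2.11 to 24.5 ± 1.11 CPM (2.0 ± 0.3, adjusted p 0.00117). Epithelial transcripts lay high in the same libraries (median 1.55 over their list). JUND, a subunit of AP-1, fell from 277 ± 47 to 72.6 ± 6.98 CPM (-1.93 ± 0.11, adjusted p 1e-10), and so did the cytokine gene CLCF1 (-1.11 ± 0.14, adjusted p 0.00022). Of 17477 genes 57 were higher and 47 lower, with 31 and 7 of at least 2-fold and a median size of 0.71 among called genes. Arms did not overlap for 16.4% (10% by chance). Scaled by library totals the calls were 78 and 17, and with DESeq2 72 and 269. Without control replicate 1, control replicate 2 or miR-497-5p replicate 3 the higher genes numbered 37, 34 and 37. The lower ones numbered 206 without control replicate 3, 101 without miR-497-5p replicate 1 and 27 without miR-497-5p replicate 3.

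Of the 33 published targets 6 were enriched in the pull-down at 12 h (8 when adjusted over the list alone; median 0.13; camera adjusted p 0.0104, adjusted p = 0.363 with an estimated correlation). They included HMGA2, from 39.6 ± 2.68 to 65.7 ± 11.9 CPM (0.73 ± 0.14, adjusted p 0.00864), and CDK6 (0.83 ± 0.18, adjusted p 0.03), whose call ended without control replicate 1 (0.0964), control replicate 2 (0.0883) or miR-497-5p replicate 1 (0.108) and in the fit of 6 libraries (0.0656). The p53 regulator MDM2 fell by 0.54 ± 0.1 (adjusted p 0.00632, and 0.0828 in the fit of 6 libraries). The list of 79 ribosomal protein genes lay low (median -0.09, and 0 when scaled by library totals; camera adjusted p 0.0038, adjusted p = 0.663 with an estimated correlation). Yet 2 of its genes were called higher and 0 lower (2 and 4 when adjusted over the list alone), with RPLP0 at 0.7 ± 0.1 (adjusted p 0.00108). Epithelial genes lay high as a list (median 1.55, camera adjusted p 7.66e-09, adjusted p = 0.035 with an estimated correlation), yet edgeR called 0 of 10 over all genes (4 when adjusted over the list alone, 5 at an unadjusted p under 0.05, 0 by DESeq2 and 5 by limma-voom). CDH1, the adhesion protein E-cadherin, went from 2.8 ± 1.66 to 13.2 ± 1.69 CPM (2.24 ± 0.59, adjusted p 0.101) and EPCAM had 2.37 ± 0.85 (adjusted p 0.3). Beyond the input both were called, as given below, in a fit that understates the spread of the pull-down. Sums of squamous markers in these pull-down libraries ran from 49.4 to 707 CPM in control and from 78.4 to 748 with miR-497-5p. The interferon list had a median of 0.29 (camera adjusted p 0.000521, adjusted p = 0.035 with an estimated correlation), with 0 of 37 called by edgeR, 4 higher and 1 lower at an unadjusted p under 0.05, 1 lower by DESeq2 and 3 higher by limma-voom.

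Of 17477 genes in the pull-down at 72 h 1776 were higher and 2194 lower. MMP1 rose from 7.1 ± 1.12 to 44.9 ± 6.63 CPM (2.67 ± 0.17, adjusted p 1.48e-11), DUSP6 by 2.42 ± 0.35 (adjusted p 9.01e-06) and SATB1, a chromatin organizer, from 3.43 ± 1.78 to 21.5 ± 3.12 CPM (2.65 ± 0.36, adjusted p 4.2e-06). UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell from 523 ± 35.1 to 147 ± 6.46 CPM (-1.83 ± 0.09, adjusted p 1.97e-13). CDCA3, a cell division gene, fell from 88.4 ± 8.72 to 18.9 ± 1.52 CPM (-2.22 ± 0.13, adjusted p 1.02e-11). Of the higher and lower genes 614 and 657 changed at least 2-fold, with a median size of 0.79 among called genes and non-overlapping arms for 35.5% (10% by chance). Across 8908 genes the fold changes of both assays correlated with r = 0.72 at 72 h, against -0.08 across 9813 genes at 12 h. Genes are not independent replicates.

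Nuclear genes of the respiratory chain formed the group with the most members lower in the pull-down at 72 h, 55 of 79 with 2 higher (58 and 2 when adjusted over the list alone; median -0.72; camera adjusted p 9.38e-21, adjusted p = 0.0342 with an estimated correlation). COX5B, a subunit of cytochrome c oxidase, fell from 1030 ± 30.5 to 363 ± 10.5 CPM (-1.5 ± 0.08, adjusted p 9.03e-13). Ribosomal protein genes had 39 of 79 lower and 10 higher (41 and 12 when adjusted over the list alone; camera adjusted p 1.15e-05, adjusted p = 0.416 with an estimated correlation). RPS26 had -1.77 ± 0.08 (adjusted p 8.41e-14). DNA replication genes had 21 of 37 lower and 2 higher (25 and 3 when adjusted over the list alone; camera adjusted p 1e-07, adjusted p = 0.0651 with an estimated correlation). G2/M genes had 20 of 40 lower and 4 higher (23 and 4 when adjusted over the list alone; camera adjusted p 1.15e-05, adjusted p = 0.126 with an estimated correlation). Inflammatory genes rose in 7 of 23 and fell in 1 (9 and 1 when adjusted over the list alone; camera adjusted p 0.000496, adjusted p = 0.0344 with an estimated correlation). IL1B had 1.44 ± 0.17 (adjusted p 5.2e-07). Published targets went both ways, 6 higher and 7 lower of 33 (6 and 7 when adjusted over the list alone; camera adjusted p 0.995). E2F3 went from 29.2 ± 5.5 to 82.4 ± 7.36 CPM (1.5 ± 0.17, adjusted p 3.54e-07) and ARL2 stood at -1.71 ± 0.13 (adjusted p 5.11e-10).

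**Figure D2:**
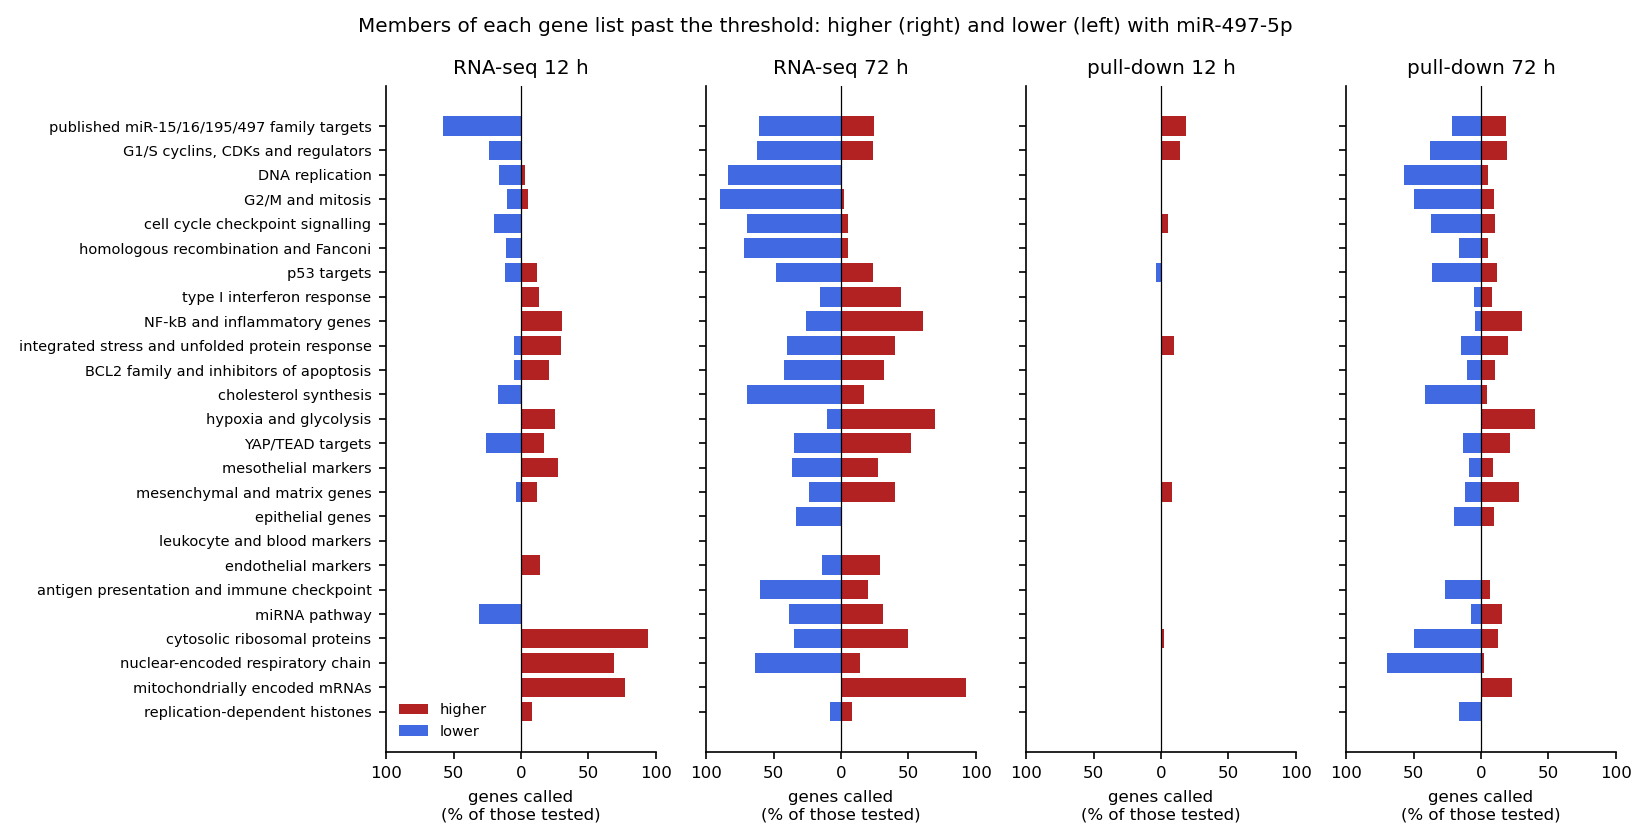
Percent of the tested members of 25 gene lists called higher (red, to the right) or lower (blue, to the left) with miR-497-5p in each of the 4 comparisons. Ribosomal protein genes are higher in 75 of 80 cases in RNA-seq at 12 h, and genes of G2/M and mitosis are lower in 36 of 40 cases in RNA-seq at 72 h.

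The series sets the transcripts bound by the microRNA beside those that change in the cell. At 12 h 15 of the 57 genes enriched in the pull-down were lower in RNA-seq, against 3.2 for independent lists (908 lower genes among 16383 tested in both; odds ratio 6.17, Fisher's exact p 3.14e-07). The mirror overlap, lower in the pull-down and higher in RNA-seq, held 8 genes against 3.6 (odds ratio 2.48, p 0.0249). Higher in both were 6 against 4.4, and lower in both 4 against 2.6. With 1 library left out of either assay the overlap ranged from 8 to 17, and it was 9 without pull-down control replicate 1 and 8 without replicate 2. It was 26 with library totals, 46 with limma-voom and 16 with a length offset in both assays. The 15 genes were CCNE1, WNT5B, CDC37L1, SPRED1, EZR, HSPA8, WEE1, RBMS1, DDR1, FBXW7, CDK6, SMC1A, BRPF3, EIF3A and FGF2. The pull-down call of RBMS1 ended without control replicate 1 (adjusted p 0.0708), control replicate 2 (0.0686) or miR-497-5p replicate 3 (0.0668). CCNE1 had 1.45 in the pull-down and -0.71 in RNA-seq, WEE1 1.71 and -0.47, SPRED1, an inhibitor of Ras signalling, 1.08 and -0.3, and the Wnt ligand gene WNT5B 0.69 and -0.5. Of the 15 genes 10 had a 7mer-m8 or 8mer site in the 3′ UTR (66.7%, against 26.2% of tested genes with an annotated 3′ UTR) and 7 an 8mer site (46.7%, against 5.2%). The lists that the 15 were drawn from already held more sites than tested genes. Shares were 56.6% and 17.5% among all genes lower in RNA-seq, and 44.6% and 21.4% among all genes higher in the pull-down. WEE1 has a 7mer-m8 site at 9588867 to 9588873 and an 8mer site at 9589146 to 9589153 of chromosome 11, and CCNE1 has 8mer sites at 29824024 to 29824031 and 29824262 to 29824269 of chromosome 19.

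At 72 h the reverse held. Only 90 genes were higher in the pull-down and lower in RNA-seq, against 542.9 for independent lists (odds ratio 0.1), a number that was 56 without pull-down miR-497-5p replicate 3, 185 with library totals and 160 with 6 libraries fitted at a time. Instead 1352 genes were higher in both, against 509.8, and 1777 lower in both, against 674.2, while 136 were lower in the pull-down and higher in RNA-seq, against 633.2. Among the 90 were PHACTR2 with 1.24 in the pull-down and -0.31 in RNA-seq, the proliferation marker MKI67 with 0.68 and -0.17 and the DNA methyltransferase DNMT1 with 0.66 and -0.59. Of the 84 with an annotated 3′ UTR 24 had a 7mer-m8 or 8mer site (28.6%, against 26.2% of tested genes with one).

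**Figure D3:**
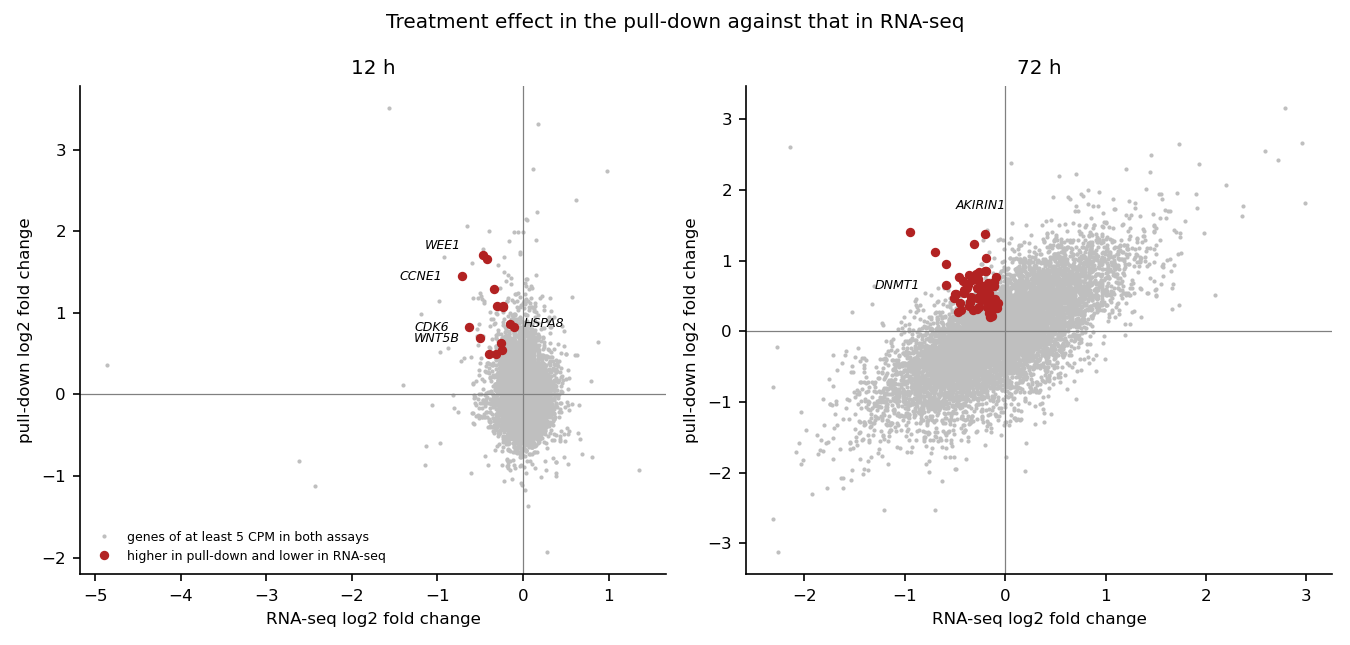
Log2 fold change with miR-497-5p in the pull-down (vertical axis) against that in RNA-seq (horizontal axis) at 12 h and 72 h, with a point for each gene of at least 5 CPM in both assays and red for genes higher in the pull-down and lower in RNA-seq. The 15 red genes at 12 h include CCNE1 and WEE1, and the points form a rising cloud at 72 h (r = 0.72) and none at 12 h (r = -0.08).

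The pull-down effect minus the RNA-seq effect gives enrichment beyond the input. Its fit at 12 h pools 1 spread over both assays, with a biological coefficient of variation of 0.2, against 0.349 over the pull-down libraries. The spread of the pull-down is thus understated: the standard error of WEE1 was 0.24 beyond the input and 0.3 in the pull-down alone. WEE1 was enriched at 12 h by 2.2 ± 0.24 (adjusted p 0.000337) and had 1.21 ± 0.43 at 72 h (adjusted p 0.0744). JUND was depleted at 12 h (-2.2 ± 0.17, adjusted p 1.79e-05). Of 10 epithelial genes 3 were enriched at 12 h, CDH1 (3.06 ± 0.65, adjusted p 0.0322) and EPCAM (2.54 ± 0.56, adjusted p 0.0354) among them. That number was 0 with the replicate block, 0 without pull-down miR-497-5p replicate 2, 1 without RNA-seq control replicate 3 and 0 without any other RNA-seq library, and 5 without pull-down miR-497-5p replicate 1 or with library totals and 6 with DESeq2 or without a filter. Among genes of at least 1 CPM in RNA-seq at 72 h, 2 of the 10 were left to test and 0 were enriched. Of the 28 squamous markers, chosen after such genes had been seen, 2 were enriched. That was 1 with the replicate block, 1 without RNA-seq control replicate 3 and 0 without any other RNA-seq library. It was 4 with limma-voom or without pull-down control replicate 3, and 21 without a filter. In control RNA-seq CDH1 averaged 4.11 CPM of total counts at 12 h and 0.0253 at 72 h, and EPCAM 3.04 and 0.737. Of 6 brain transcripts with a like fall 0 were enriched, against 5 without pull-down miR-497-5p replicate 1, 1 without control replicate 2 or with DESeq2 and 6 without a filter. Of 14 further brain markers tested 0 were enriched, against 4 without pull-down miR-497-5p replicate 1 and 2 with DESeq2, library totals or limma-voom. These genes do not stand for all transcripts nearly absent at 72 h: SPARCL1, chosen after its value was seen, was enriched (1.74 ± 0.28, adjusted p 0.00702). Nor do the lists hold every enriched gene of neural or epithelial tissue. Further examples, also chosen after their values were seen, were SLC1A3 (1.94 ± 0.27, adjusted p 0.00212) and GPM6A (1.71 ± 0.4, adjusted p 0.0493) of neural tissue. The claudin genes CLDN6 (3.08 ± 0.56, adjusted p 0.0174) and CLDN7 (2.11 ± 0.49, adjusted p 0.0453) were enriched too. Of 17078 genes 168 were enriched and 61 depleted at 12 h. Each left-out RNA-seq library took these numbers to between 36 and 49 and between 6 and 10, and left-out pull-down libraries to 111 enriched and 23 depleted (control replicate 2), 468 and 215 (miR-497-5p replicate 1), 224 depleted (control replicate 3) and 165 depleted (miR-497-5p replicate 2). Scaling and test also moved the split, to 127 and 116 with DESeq2-style size factors, 367 and 33 with library totals, 392 and 582 with DESeq2 and 403 and 328 with limma-voom. Fold changes at 12 h rose with transcript length in the pull-down (Spearman rho 0.129 ± 0.007) and fell with it in RNA-seq, and with a length offset 111 were enriched and 47 depleted. At 72 h 1260 of 16896 genes were enriched and 1185 depleted, or 2085 and 747 with library totals. TUBA1B, an alpha tubulin, had fallen in RNA-seq (-2.27 ± 0.04, adjusted p 6.34e-30) and had 1.99 ± 0.22 beyond the input (adjusted p 9.03e-06). The contrast also rises when only the input falls, and its size here is near that of the fall. The value of TUBA1B thus need not mean that more of it was retained. CCND1 was enriched by 0.54 ± 0.05 (adjusted p 1.25e-06). CSTF3, a cleavage stimulation factor subunit, was depleted (-2.2 ± 0.17, adjusted p 1.15e-07).

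Sites for the miR-497-5p seed separated genes in RNA-seq at 12 h. Genes with a 7mer-m8 or 8mer site lay 0.085 below genes without a 6mer site (seed effect -0.085 ± 0.004), the lowest of 210 words of the same base composition, and rank 97 of 16278 among all words of 7 bases. Matched on 3′ UTR length it was -0.04 (share of words 0.01). Median log2 fold changes by best site were 0.034 for genes without a site, -0.007 for 6mer, -0.048 for 7mer-A1, -0.041 for 7mer-m8 and -0.096 for 8mer sites. Of 722 genes with an 8mer site 157 fell and 22 rose (176 and 29 when adjusted over the list alone). Their camera p was 1.66e-10, and 0.000491 with an estimated correlation, neither adjusted over lists. Among genes with an annotated 3′ UTR, a 7mer-m8 or 8mer site was present in 507 of 895 lower genes (56.6%) and in 146 of 1162 higher genes (12.6%), against 26.2% of tested genes. Lower genes with an 8mer site include CCND1 (chromosome 11, 69653315 to 69653322) and CDC25A (chromosome 3, 48158264 to 48158271).

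In the pull-down at 12 h the seed effect was 0.026 ± 0.007, and a share of 0.481 of the words was as extreme. With 8mer sites alone it was 0.109 (share 0.019), and matched on 3′ UTR length -0.01 (share 0.748). Genes with an 8mer site had a median of 0.094, with 12 higher and 4 lower (camera p 0.00393, and 0.0108 with an estimated correlation, neither adjusted over lists). Of 56 enriched genes with an annotated 3′ UTR 25 carried a 7mer-m8 or 8mer site (44.6%). So did 16 of 45 depleted genes (35.6%), against 26.2% of tested genes. Beyond the input the seed effect at 12 h was 0.109 ± 0.011 (share of words 0.071), with a median of 0.217 for genes with an 8mer site. There 76 of 165 enriched genes with an annotated 3′ UTR carried a 7mer-m8 or 8mer site (46.1%). So did 17 of 60 depleted genes (28.3%), against 26.3% of tested genes. At 72 h the seed effect was -0.048 ± 0.013 in RNA-seq (share of words 0.438) and 0.016 ± 0.018 in the pull-down (share 0.929). Matched on 3′ UTR length these became -0.228 (share 0.033) and -0.141 (share 0.048), so a seed effect at 72 h depended on that matching. Sites were present in 27.7% of lower and 25.7% of higher genes in RNA-seq, among those with an annotated 3′ UTR.

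**Figure D4:**
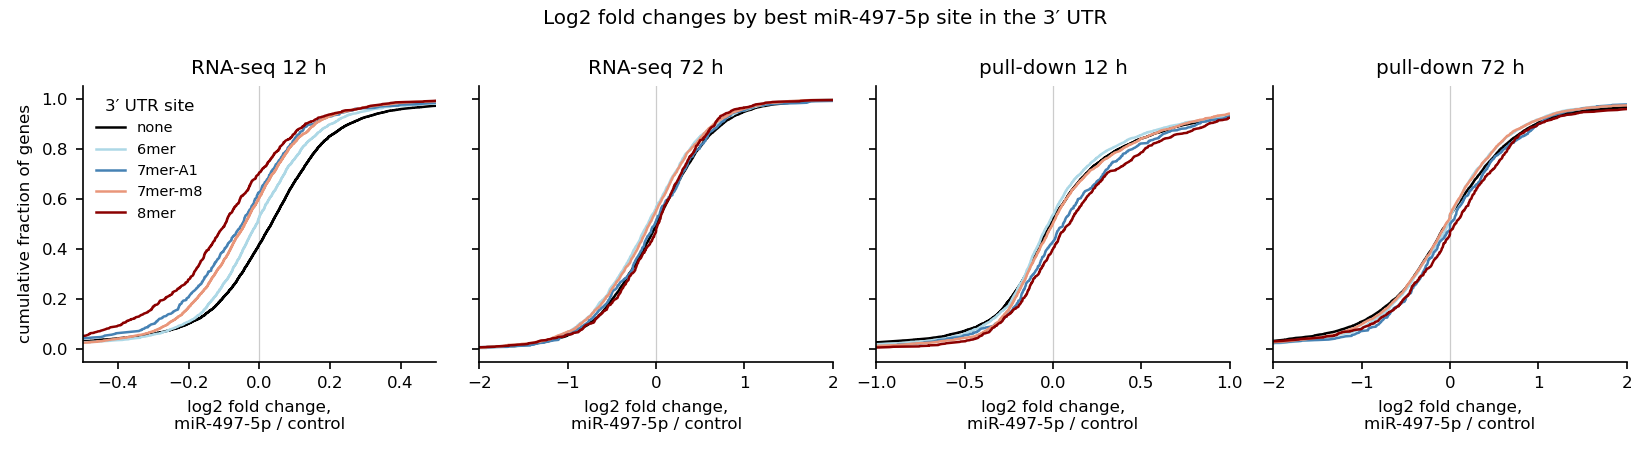
Cumulative fraction of genes (vertical axis) against log2 fold change with miR-497-5p (horizontal axis, truncated at a size of 0.5, 2, 1 and 2 in the 4 panels), by the best seed site in the 3′ UTR, for each assay and time. In RNA-seq at 12 h the curves are ordered from 8mer (median -0.096) to no site (median 0.034).

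The effect of miR-497-5p was compared between the times directly. In RNA-seq 8451 genes differed, 3902 with a higher effect at 72 h and 4549 with a lower one, and in the pull-down 2134 differed, 1038 and 1096 (854 and 1407 when scaled by library totals). CDK4 differed by -1.99 ± 0.06 in RNA-seq (adjusted p 9.29e-30), PKMYT1 by -2.34 ± 0.13 (adjusted p 1.8e-20) and WEE1 by -0.48 ± 0.11 (adjusted p 0.000304). Called at both times in RNA-seq, 580 genes were higher at 12 h and lower at 72 h (371.5 for independent lists) and 318 the reverse (256.3), while 415 were higher (350.3) and 402 lower (271.9) at both, so all 4 numbers exceeded independence. Both times' effects came from separate libraries. CCND1, lower at 12 h, had a difference of 0.35 ± 0.04 (adjusted p 3.68e-09), and GAPDH one of 0.58 ± 0.04.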

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

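The test of a length trend in the input and the test of an effect of miR-497-5p on squamous genes, both below, were chosen only after the result was seen. Results in this part stood out because the effect of miR-497-5p differed between 12 h and 72 h by the edgeR test of that difference. In RNA-seq 8451 genes differed. The effect at 72 h lay furthest above that at 12 h for KRTAP1-5 (2.85 ± 0.17), MMP1 (2.68 ± 0.06), SERPINB2 (2.65 ± 0.09), DUSP6 (2.49 ± 0.16) and CLDN1 of tight junctions (2.42 ± 0.11). It lay furthest below for CYP26B1, which degrades retinoic acid (-2.4 ± 0.19), TUBA1B (-2.37 ± 0.05), CKS1B (-2.35 ± 0.06), PKMYT1 (-2.34 ± 0.13) and PKD1P5 (-2.34 ± 0.2), a pseudogene whose reads are hard to tell from those of PKD1. Of the other genes that the series names, CDK4 differed by -1.99 ± 0.06, WEE1 by -0.48 ± 0.11, CCND1 by 0.35 ± 0.04 and GAPDH by 0.58 ± 0.04. VEGFA differed by -0.26 ± 0.1 (adjusted p 0.0332), and this call ended with DESeq2 (0.0825), limma-voom (0.0582) or no filter on low counts (0.053) and when any of 6 libraries was left out. At 12 h the adjusted p was 0.0611 and 0.0987 without control replicates 2 and 3 and 0.0698 without miR-497-5p replicate 1. At 72 h it was 0.13 without control replicate 3 and 0.131 and 0.0686 without miR-497-5p replicates 1 and 2.

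In the pull-down 2134 genes differed between the times. Above were NSRP1P1, a pseudogene (4.12 ± 1.15, adjusted p 0.719 without control replicate 2 at 12 h), JPH1 (2.87), SATB1 (2.78 ± 0.49), CDH15, a cadherin (2.61), and NCKAP5 (2.31, adjusted p 0.0511 and 0.0549 without control replicates 1 and 2 at 12 h). Among those below were the chloride channel gene CFTR (-4.32 ± 0.67), the neuronal kinesin gene KIF1A (-4.17 ± 1.05), KRT80 (-3.07 ± 0.46) and ZNF597 (-2.82). KIF1A, with a mean of 17.6 CPM in control RNA-seq at 12 h, is among the genes nearly absent at 72 h, as are the brain transcripts weighed below, and its adjusted p was 0.0575 and 0.0513 without control replicates 1 and 3 and 0.058 without miR-497-5p replicate 3 at 72 h. PKMYT1 differed by -2.23 ± 0.35, CCND1 by 0.83 ± 0.13, GAPDH by 0.77 and CDK4 by -0.94 ± 0.24 (adjusted p 0.0667 without miR-497-5p replicate 1 at 72 h). WEE1 differed by -1.42 ± 0.44 (adjusted p 0.0332). That call ended without control replicates 2 and 3 (0.0618 and 0.0722) and miR-497-5p replicate 1 (0.101) at 12 h, and without control replicates 2 and 3 (0.0507 and 0.106) and miR-497-5p replicates 2 and 3 (0.0681 and 0.0795) at 72 h. With limma-voom the calls of NSRP1P1 (0.285), KIF1A (0.43), CDK4 (0.0968) and WEE1 (0.0552) ended too.

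Other splits of the same libraries were counted for these results. In RNA-seq 2 of 100 drawn splits gave as many genes with a different effect, the real one with 8451 and another with 14361. Further splits came close with 8171, 8112 and 8034. In the pull-down 5 of 100 splits did, the real one with 2134 and others with 11584, 4559, 4387 and 4247. In both assays these large counts point to a structure of the samples, which differ by time. Each of those splits exchanged the times of all 6 libraries in 1 arm and of 0 or 2 in the other, which turns a difference between the times into an apparent difference of effects. Splits that exchanged no arm as a whole gave at most 3024 genes in RNA-seq and 0 in the pull-down, a grouping of splits made after their counts were seen. Those splits mixed libraries of 12 h and 72 h in 1 group, which can widen the spread and lower the count. The shares of 2 in 100 in RNA-seq and 5 in 100 in the pull-down therefore decide nothing.

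The first pattern weighed is transcript length. In RNA-seq at 12 h fold changes fell with exonic length across genes (Spearman rho -0.252 ± 0.007), whereas rho was 0.129 ± 0.007 in the pull-down at 12 h, of the opposite sign to its input. At 72 h rho was 0.082 ± 0.008 in the pull-down and 0.055 ± 0.008 in RNA-seq, so the trend of the 72 h pull-down, unlike that at 12 h, is consistent with 1 already present in the input. Seed sites in long 3′ UTRs are argued against, since rho in the pull-down at 72 h over genes without a 6mer site was 0.166, beside 0.169 over all genes with a 3′ UTR. Length is also argued against as the whole cause of the calls: with a length offset 3403 of the 3970 calls of the pull-down at 72 h (85.7%) kept their direction, and in RNA-seq at 12 h, with the replicate block, the median of the 80 ribosomal protein genes was 0.151 with the offset and 0.22 without it, and 66 of the 80 were called higher with it. What stays open is whether length bias of the libraries or an effect of miR-497-5p on long transcripts, which the design does not separate, produced the trend.

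The next pattern is RNA of other tissues at 12 h. Squamous markers rose and fell together over the 12 libraries at 12 h (median Spearman rho 0.751 over 378 pairs), which is consistent with RNA of squamous epithelial cells in varying amounts. Single markers departed from this: miR-497-5p replicate 1 had the highest marker sum in both assays, yet KRT13 stood at 1.33 CPM in its pull-down library and SPRR3 at 1.04 in its RNA-seq library, against 14.7 to 22.9 in the RNA-seq controls. One source of fixed composition is therefore not shown. In RNA-seq 12 of the 28 markers (42.9%) were lower in all 3 libraries with miR-497-5p than in all 3 control ones, and in the pull-down 0.0% were. The pull-down value decides nothing, since marker sums ran from 49.4 to 707 CPM of total counts within its control arm and from 78.4 to 748 within the other, and a bound transcript would be higher there. Whether miR-497-5p also lowered these genes cannot be told apart from unequal amounts of such RNA. The most abundant, KRT13, reached 161, 133 and 50.1 CPM of total counts in the control RNA-seq libraries at 12 h and at most a mean of 0.264 at 72 h, and 2 of the 28 reached 1 CPM in RNA-seq at 72 h. For brain, 8 of 20 markers were higher in every RNA-seq library at 12 h than in every one at 72 h and 2 were lower, so RNA of brain tissue and a difference of the cells between the times cannot be told apart, because too few markers moved either way.

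The last pattern asks whether the control mimic acted through a seed of its own, since its sequence is not given. cel-miR-67 is a candidate identity, with the sites GGTTGTG and GGTTGTGA. Genes with its 8mer site were the highest of 35 words in RNA-seq at 12 h after matching on 3′ UTR length (0.072), which argues against UTR length as the source of that rank. Among all words of 7 bases, without matching, GGTTGTG ranked only 1600 of 16278 from the highest there and 4750 of 16284 in the 12 h pull-down. Beyond the input at 12 h they lay 0.025 under the median of the other 34 words (difference -0.025), and a bound at 0 decides nothing, since all 34 words lay above 0. Genes with the 7mer-m8 site were the highest of the 35 words in the 12 h pull-down not set against the input (0.055 ± 0.012) and those with the 8mer site ranked 2 (0.086 ± 0.021), where retention by the control mimic alone would lower them. Both sites also ranked highest in RNA-seq at 12 h, so the input may enter these ranks. Its unmatched differences were -0.025 ± 0.005 (7mer-m8) and 0.006 ± 0.011 (8mer), neither above 0 by more than its standard error. A seed effect of the control mimic and its absence cannot be told apart on the value beyond the input.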

How the results depend on the processing

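Alternatives with a length offset or restricted to genes of at least 1 CPM in RNA-seq at 72 h were chosen only after the result was seen. Counts that kept within 1.5 times under every alternative and left-out library were those of genes higher and lower in RNA-seq at 72 h and in the pull-down at 72 h and of both differences between the times. Pull-down libraries varied more than RNA-seq ones (coefficient of biological variation 0.349 against 0.06), and fewer simulated changes were recovered in them. Comparisons between assays share 1 spread between quiet RNA-seq and variable pull-down libraries, so that of the pull-down is understated there. The fits of each assay likewise share 1 spread between the times. In RNA-seq the chi-square per degree of freedom was 2.94 to 8.45 at 12 h and 1.77 to 2.76 at 72 h. In the pull-down it was 7.1 to 32.5 and 7.2 to 13.74. Adjusted p-values at 12 h may therefore be too small. With 6 libraries fitted at a time, 13 of 98 named calls in RNA-seq at 12 h became weaker. DESeq2 gives no adjusted p for genes its filter removes, WEE1 in the pull-down at 12 h among them. Over the named genes and alternatives 7633 values kept direction and side of the threshold, 354 became weaker, 140 stronger and 1 reversed. Fewer calls held throughout: of the named calls 40 of 98 in RNA-seq at 12 h, 5 of 117 in RNA-seq at 72 h, 12 of 32 in the pull-down at 12 h, 11 of 108 in the pull-down at 72 h, and 8 of 11 and 4 of 13 beyond the input at 12 h and 72 h ended in at least 1 alternative or left-out library. Where a result below did not keep, the cause was not tested, except that leaving out a library lowers the number of samples.

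With library totals in place of TMM, RNA-seq at 12 h gave 722 higher and 1746 lower genes, the pull-down at 12 h 17 lower, enrichment beyond the input 367 enriched and 33 depleted at 12 h and 2085 and 747 at 72 h, and the overlaps 26 genes at 12 h and 185 at 72 h. CCND1 in RNA-seq at 72 h turned to -0.07 (adjusted p 0.023, with a range of 0.0032 to 1 over its alternatives). With DESeq2 the pull-down at 12 h gave 269 lower, and the contrast between assays at 12 h 392 enriched and 582 depleted. With DESeq2-style size factors that contrast gave 116 depleted. Without a filter on low counts the pull-down at 12 h gave 108 higher and 109 lower and the contrast 397 and 176. Fitting 6 libraries at a time gave 12 lower in the pull-down at 12 h and an overlap of 160 at 72 h. With a length offset the contrast between assays at 12 h gave 111 enriched. With limma-voom the pull-down at 12 h gave 298 higher and 328 lower, the contrast 403 and 328, and the overlap 46 at 12 h.

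Leaving out 1 library at a time gave 590 (control replicate 2) to 988 lower genes in RNA-seq at 12 h, 34 to 68 higher and 27 to 206 lower in the pull-down at 12 h, 36 to 468 enriched and 6 to 224 depleted beyond the input at 12 h, and overlaps of 8 to 17 at 12 h and 56 to 84 at 72 h. The libraries that moved these counts are named beside them in the results.

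Matching on 3′ UTR length took the seed effect at 72 h to -0.228 in RNA-seq and to -0.141 in the pull-down, both past the threshold, and reversed the latter. With 8mer sites alone it was 0.109 in the pull-down at 12 h, past its threshold. With an estimated correlation 3, 4, 2 and 2 gene lists passed in RNA-seq at 12 h and 72 h and in the pull-down at 12 h and 72 h.

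With the replicate number as a block, RNA-seq gave 1375 higher and 1005 lower genes at 12 h and 4852 and 5139 at 72 h, and the pull-down 54 and 41 at 12 h and 1673 and 2109 at 72 h. Beyond the input the block gave 113 enriched and 45 depleted at 12 h, where 3 of 11 named calls ended, and 1110 and 1014 at 72 h, where 1 of 13 did. In RNA-seq at 12 h, where the numbers were taken to pair the samples, the block changed no call of the text other than that of SPRR3. At 72 h the block ended the list calls of ribosomal proteins (0.0584) and of WEE1 with PKMYT1 (0.0523) in RNA-seq. Same-numbered RNA-seq libraries of the 2 arms at 12 h gave correlations of 0.13, 0.12 and 0.52, so only replicate 3 stood out. Replicate 2 correlated more with another number (0.17). Same-numbered libraries of other pairs of groups gave -0.19 to 0.15. The labels do not say that the numbers pair the samples.

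The 6 libraries of a comparison give 10 splits, too few for a share under 0.05. In 1 of the 10 splits, the real one, the number of called genes was as large, with 2175 against at most 42 in RNA-seq at 12 h, 9963 against 0 at 72 h, 104 against 3 in the pull-down at 12 h and 3970 against 1 at 72 h. For RNA-seq at 12 h the 4 splits that part all pairs gave at most 5 besides the real one. Seed effects were the largest in 1 of the 10 splits each, with a size of 0.085 against 0.042 and 0.048 against 0.02 in RNA-seq and 0.026 against 0.017 and 0.016 against 0.015 in the pull-down. Lists past the threshold numbered 14 against at most 5, 13 against 8 and 12 against 4 (1 of the 10 splits each), and 5 against 7 in the pull-down at 12 h (3 of the 10 splits). Between assays 1 of 100 drawn splits gave as many genes at 12 h (229, against at most 118) and 2 of 100 at 72 h (2445, against at most 7330). These splits redrew the mimics within each assay, so they also broke any effect that both assays share. Nearly all mixed miR-497-5p and control libraries in 1 group, which can widen the spread and lower the count. The shares thus cannot test the difference between assays and decide nothing. The split with 7330 exchanged the arms of all 6 RNA-seq libraries and of 0 pull-down ones, so it adds the effects of both assays and points to a structure of the samples. Overlaps were as large in 1 of 100 pairs of splits at 12 h (15, against 2) and 1 of 100 at 72 h (90, against 1). These counts decide nothing, since of the 99 other pairs 1 at 12 h and 0 at 72 h called enough genes to reach the real overlap.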

Other observations

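Some gene lists with called members have no place in the comparisons above. The interferon response genes split in RNA-seq at 72 h, with 17 of 38 higher and 6 lower (17 and 6 when adjusted over the list alone; camera adjusted p 0.0553). IFIT2 and IFIT3, which bind foreign RNA and its sensors, rose by 1.66 and 1.32. Of 15 antigen presentation genes 9 were lower and 3 higher (9 and 3 when adjusted over the list alone; camera adjusted p 0.124), among them PSMB9 of the immunoproteasome (-1.25) and the class I gene HLA-C (-0.79). YAP and TEAD target genes went both ways, 12 higher and 8 lower of 23 (12 and 8 when adjusted over the list alone; camera adjusted p 0.216), with the tissue factor gene F3 at 1.35 ± 0.05 (adjusted p 2.51e-28) and ANKRD1 at 1.62. The microRNA pathway had 4 higher and 5 lower of 13 (4 and 5 when adjusted over the list alone, 1 and 6 when scaled by library totals; camera adjusted p 0.676), with TARBP2, a partner of Dicer, at -1.44.

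Among 19 genes of the BCL2 family and inhibitors of apoptosis, 6 rose and 8 fell in RNA-seq at 72 h (6 and 9 when adjusted over the list alone; camera adjusted p 0.889). The survival genes MCL1 (0.82) and XIAP (0.93) were higher, and the cell death gene BAX (-0.47) was lower. In the pull-down at 72 h, p53 targets had 9 of 25 lower and 3 higher (12 and 3 when adjusted over the list alone; camera adjusted p 0.0159, adjusted p = 0.128 with an estimated correlation), including the proapoptotic gene BBC3 (-1.1). Mesothelial markers in RNA-seq at 72 h had 3 higher and 4 lower of 11 (3 and 4 when adjusted over the list alone; camera adjusted p 0.889), with the keratin genes KRT19 at 0.59 and KRT7 at -0.36.

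Some transcripts were present at 12 h alone. In control RNA-seq libraries 21 genes reached 5 CPM of total counts in all 3 libraries at 12 h and stayed under 0.5 in all 3 at 72 h, and 1 gene, MYH7 of cardiac muscle, did the reverse (mean 8.18). Among transcripts seen at 12 h, GFAP of astrocytes had a mean of 92.7 CPM, NEFL of neurons 53.4, the basal keratin KRT5 87.9 and KRT14 70.6, all chosen after their values were seen. E-cadherin (CDH1) in the pull-down at 12 h was 3.18 ± 1.9 CPM of total counts in control and 16 ± 2.64 with miR-497-5p, and fibronectin (FN1) 164 ± 88.1 and 776 ± 29.3, while FN1 in RNA-seq was 278 and 274. Restricted to genes of at least 1 CPM in RNA-seq at 72 h, a choice made after the data were seen, RNA-seq at 12 h gave 1481 higher and 952 lower genes and the pull-down at 12 h 67 and 44.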
